A study of Mus musculus with 7 samples.

How the data were processed

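Tumour-associated macrophages were sorted by flow cytometry from intracranial QPP7 gliomas. Per the labels' protocols, tumours were dissociated for 15 min at 37 °C with collagenase IV, red cells were lysed, and Fc receptors were blocked before staining. The antibodies of the gate are not given in the sources used here. Full-length cDNA was made from 10 ng of RNA with a SMART-Seq ultra low input kit, and libraries from 1 ng of cDNA with Nextera XT, which does not mark strand. Low input and many amplification cycles add noise that counting intervals do not cover, and PCR copies are not independent molecules. Reads of a gene and of one that overlaps it on either strand cannot be told apart.

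The deposited values are whole-number counts per gene, 1 file per library, with exon coordinates and gene lengths. Trim Galore, HISAT2, featureCounts and the mm10 build are named in the submitters' processing notes, and versions, settings and annotation are not given in the sources used here. Each file lists 55385 gene IDs. Of these, 54487 matched GENCODE mouse release 21 with version, and all 54487 had the same coordinates and strand. Ignoring version, 55144 matched, and 241 IDs had no name and took under 0.002% of reads in every library. Chi3l1 is listed in that release under another symbol of the same gene, Chil1.

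Groups and replicate numbers were taken from the sample titles. No library was left out of the main comparison, and no pair of libraries agreed within sampling noise: chi-square per gene, over genes with at least 50 reads, was at least 138.6 for each of the 21 pairs. Counts were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood F test with robust estimation in R 4.3.3, over all 7 libraries with hairpin as the only term. P-values were adjusted by the Benjamini-Hochberg method over 15448 genes. CPM were computed from the TMM-scaled totals, and 0.5 was added to counts before logarithms were taken. Standard errors of a single gene's log2 fold change were derived from the F statistic. Those of a mean over markers or list members were taken over these genes, and those of score differences over libraries.

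The 29 gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and at least 5 tested members, and adjusted over the lists. Camera asks whether a list moved against the other genes. An estimated correlation and fry were run beside it, and the latter tests a list alone. A list score is the mean over members of log2 CPM centred on each gene's mean. Scores and library measures were compared with exact two-sided permutation tests over the 35 splits of 7 libraries into 3 and 4.

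Genes were named by a rule fixed, like the lists and the main design, before the data were examined. It took Chi3l1, Lgals3 and Lgals3bp, and, in each direction, 10 genes that passed or, where fewer passed, those of smallest unadjusted p, with a mean log2 CPM of at least 2, an established symbol and no overlap between groups. It added the 3 members of smallest unadjusted p of each biology or quality list, and the most abundant member and the one of smallest p of each list for another cell type.

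The labels call replicates 1 to 3 pairs in one of the study's figures, without stating a shared day, litter or animal. Deviations from the group means correlated at 0.306, 0.26 and 0.188 across genes within the same-numbered pairs, all above the limit of 0.1 set for pairing. However, shChi3l1 3 with shSC 2, at 0.322, and shChi3l1 2 with shSC 4, at 0.2, also exceeded that limit. After removal of each library's trend with transcript length the 3 same-numbered values were 0.205, 0.146 and 0.211. The main comparison left the pairing out, and the replicate number entered only in alternatives to it. A fit with the replicate block used the 6 paired libraries and left out shSC 4.

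Alternatives fixed in advance were DESeq2 size factors, upper quartile factors, no low-count filter, a filter of at least 10 counts in every library of a group, leaving out each library, the replicate block, DESeq2 1.42.0's Wald test, voom with sample quality weights, a minimum fold of 1.5, an estimated correlation, and lists without shared members. Added after the data had been seen were the removal of shChi3l1 3 and shSC 4 together, lists without members of which another gene overlaps over 25% of the exon bases, offsets for each library's loess trend (span 0.5) with transcript length, with and without the block, and covariates for the share of reads in genes over 5000 bases and in ribosomal protein genes.

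The test was checked on counts simulated for this comparison over 15448 genes, with the real means, library sizes and dispersions and 50 genes changed at each fold. Changed genes had a mean log2 CPM of at least 2. Counts were drawn independently for each gene and library, with no pairing or length trend. It called 4% of genes changed 2-fold, 20% changed 4-fold, 84% changed 8-fold and 96% changed 16-fold, with 1 false call among 103. With the dispersion scaled to 0.1 of its value, 94% to 100% were called, with 14 false among 225. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.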

Results

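Messenger RNA was profiled in macrophages sorted from intracranial gliomas of C57BL/6 mice. The tumours grew from QPP7 glioma cells, of which 100000 were injected per mouse. The injected cells carried either a hairpin against Chi3l1 (shChi3l1, 3 libraries) or a control hairpin (shSC, 4 libraries). Chi3l1 encodes chitinase-3-like-1, a secreted glycoprotein that binds chitin but does not cleave it. The hairpin was in the tumour cells and not in the macrophages, so the comparison asks how macrophages differed between tumours of the 2 hairpins, in a study of Chi3l1 and immune suppression by macrophages in glioblastoma. Reads assigned to genes numbered 29239011, 36502664 and 23174989 in shChi3l1 replicates 1, 2 and 3. In shSC replicates 1 to 4 they numbered 31067984, 32590781, 27842802 and 19169129. The labels do not state that each library came from a separate mouse, so the single-gene p-values measure the spread between these libraries, part of which may be technical. Camera's p-values at the preset correlation instead set a list's genes against the other genes. They assume that a list's genes hardly move together between libraries.

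Chi3l1 transcripts were scarce in the sorted macrophages of both groups. Chi3l1 (ENSMUSG00000064246.10, mm10 chromosome 1, 134182176 to 134190181, plus strand) had 0.799 ± 0.466 CPM (SD, n = 3) in shChi3l1 and 0.800 ± 0.021 CPM (SD, n = 4) in shSC libraries. These levels rest on 28, 31 and 7 reads in the shChi3l1 libraries and 18 to 28 reads in the shSC libraries. The log2 fold change was 0.00 with a standard error of 0.66, and with so few reads and that spread no difference was detectable. Because the hairpin acted in other cells, this value is only an indirect check of the labels. Lgals3, which encodes galectin-3, was abundant at 2536 ± 1300 CPM (SD, n = 3) in shChi3l1 and 2529 ± 640.4 CPM (SD, n = 4) in shSC libraries. Lgals3bp, encoding the galectin-3 binding protein, had 2322 ± 2040 CPM (SD, n = 3) against 1159 ± 673.7 CPM (SD, n = 4). Its log2 fold change of 1.00 (SE 0.68) had an edgeR adjusted p of 0.9998. The list of 11 tested genes of the chitinase-3-like-1 and galectin-3 axis did not move as a group (camera adjusted p = 0.974), with 5 members higher and 6 lower, a mean log2 difference of 0.075 and an edgeR median just below 0. Sdc1, a cell-surface proteoglycan, had the smallest unadjusted p in that list, with a log2 fold change of 1.33 (SE 0.59). Sdc4, of the same family, was at -0.71 (SE 0.49).

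No single gene passed the adjusted threshold over all 15448 tested genes, which does not show that none differed. At the adjusted threshold of 0.05, edgeR's quasi-likelihood test called 0 genes, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 229 genes, 140 higher and 89 lower in shChi3l1, where chance alone gives 772 on average. Unadjusted p lay above 0.9 in 2257 genes and at or below 0.1 in 528, so p-values ran higher than an even spread would give. The low count is therefore no evidence that genes did not change. Limma's voom with sample quality weights also called 0, with 713 at an unadjusted p under 0.05. DESeq2's Wald test had 350 at that level and called 1 gene, the immunoglobulin light-chain segment Igkv4-58 (adjusted p = 2.6e-05), which was chosen after its values were seen. It had 60, 42 and 35 reads in the shChi3l1 libraries and 0 in each shSC library, which makes it at least 64.9-fold higher against a floor of 3 counts over the shSC group. Such segments belong to a family of similar genes, so its reads are uncertain, and the floor covers counting error only. The groups did not overlap in 191 genes that were higher and 193 that were lower in shChi3l1. That is 2.49% of the tested genes, and chance gives 5.71% for 3 libraries against 4. The common dispersion was 0.341, a biological coefficient of variation of 58.3%. At the observed dispersions, simulated 2-fold changes were called in 4% of genes.

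Among the genes that separated the groups, the 10 higher ones of smallest unadjusted p were led by Hpgd (ENSMUSG00000031613.9, chromosome 8, 56294585 to 56321043), which encodes the enzyme that inactivates prostaglandin E. Hpgd had 20.2 ± 14.4 CPM (SD, n = 3) in shChi3l1 and 3.85 ± 1.60 CPM (SD, n = 4) in shSC libraries, a log2 fold change of 2.39 (SE 0.54). Plk3, a stress-responsive kinase, was at 1.51 (SE 0.36), and Timp2, an inhibitor of matrix metalloproteinases, at 1.71 (SE 0.42). Agmo, the alkylglycerol monooxygenase, had a log2 fold change of 2.06 (SE 0.55). The purinergic-type receptor gene Gpr34, a microglial marker, was at 2.03 (SE 0.59). Cd33, a sialic acid-binding receptor of myeloid cells, was at 0.96 (SE 0.31). The other 4 were Zfand5, Rgmb, Tapt1 and Rnf11, with log2 fold changes of 0.98, 1.08, 1.11 and 1.15. Of the 10 lower genes, the glucose transporter gene Slc2a3 had 2.61 ± 0.772 CPM (SD, n = 3) against 7.87 ± 2.95 CPM (SD, n = 4), a log2 fold change of -1.59 (SE 0.48). Knstrn, a spindle protein gene, was at -0.99 and Aurkb, the aurora B kinase gene, at -1.06. Rad51ap1, which acts in recombination repair, had 3.44 ± 0.564 CPM (SD, n = 3) against 6.90 ± 1.98 CPM (SD, n = 4). Shmt1 (-1.17) and Asns (-1.12) encode enzymes of serine-glycine and asparagine metabolism. Rhov (-1.17), Gsdme (-1.03), the long noncoding Pvt1 (-1.46) and the myeloid receptor gene Cd300e (-1.17) completed the set. All 20 had an edgeR adjusted p of 0.9998.

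**Figure D1:**
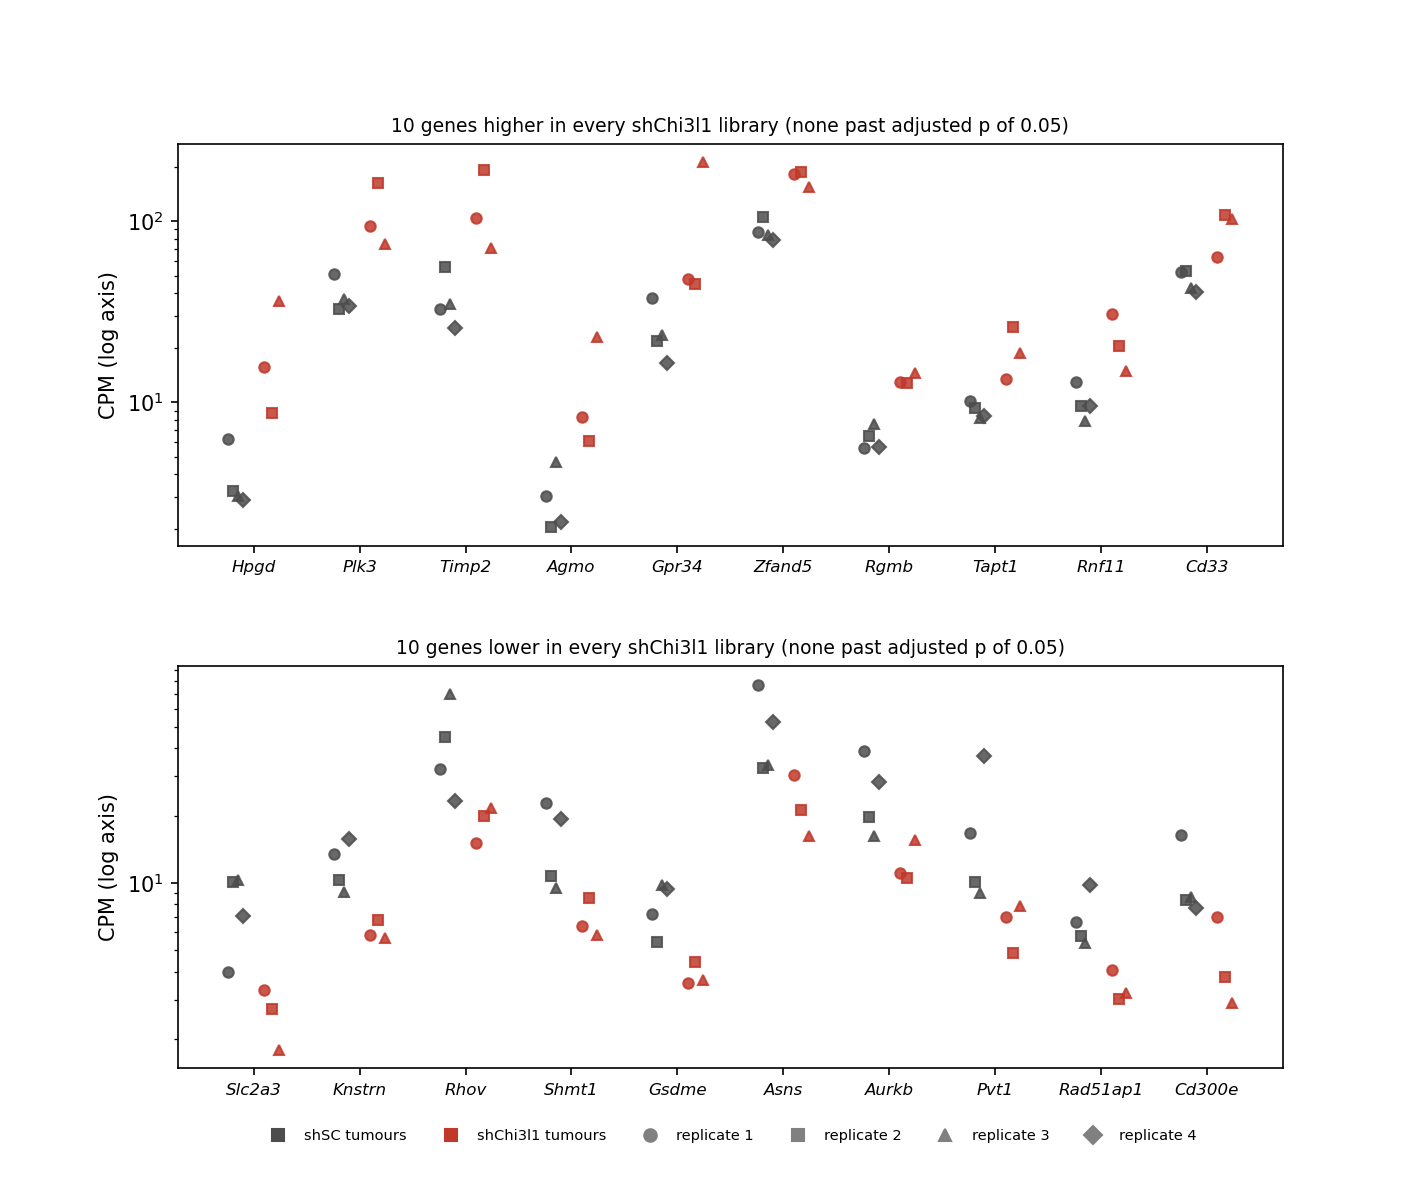
CPM (log axis) of the 10 genes of smallest unadjusted p among those higher (upper panel) and lower (lower panel) in every shChi3l1 library than in every shSC library. Each point is 1 library, coloured by group and shaped by replicate number. Hpgd lies between 8.71 and 36.3 CPM in shChi3l1 and between 2.88 and 6.24 CPM in shSC libraries, and none of the 20 genes passed the adjusted threshold of 0.05.

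Groups of genes were then compared through 29 lists of functions and cell types. With camera's preset correlation between genes, 7 lists passed an adjusted p of 0.05, 5 of them higher and 2 lower in shChi3l1. With an estimated correlation none of the 29 passed, and fry called 0 lists for direction and 0 for change in either direction. Each passing list is given with its adjusted p under both. Medians are of edgeR's log2 fold changes unless stated, whereas camera's tests and the mean log2 differences use voom values.

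Cell proliferation genes fell as a group in macrophages from shChi3l1 tumours. All 25 tested members were lower, with a median log2 fold change of -0.72 and an adjusted p of 8.1e-17. With an estimated correlation its adjusted p was 0.288. Aurkb, Aurka and Mcm5 had the smallest unadjusted p, with log2 fold changes of -1.06 (SE 0.40), -0.80 (SE 0.33) and -0.74 (SE 0.31). Aurka encodes a mitotic kinase and Mcm5 a subunit of the replicative helicase. No member passed adjusted over all genes or adjusted over the list alone. The list score, the mean of gene-centred log2 CPM, was -0.376 ± 0.109 (SD, n = 3) in shChi3l1 and 0.282 ± 0.392 (SD, n = 4) in shSC libraries. Every shChi3l1 library lay below every shSC library, which gave an exact two-sided permutation p of 0.0571, the smallest that 3 libraries against 4 allow. The score was highest in shSC 4, the library also highest in tumour and glial markers, at 0.781.

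Microglia homeostatic genes rose as a group, and shChi3l1 replicate 3 carried most of the difference. All 15 members were higher, with a median log2 fold change of 1.39 (1.075 on voom values) and an adjusted p of 3.97e-13. An estimated correlation gave an adjusted p of 0.42. Adjusted over the list alone, 4 members passed: Slc2a5, a fructose transporter gene, at 4.09 (SE 1.08), Siglech at 3.53 (SE 1.00), the purinergic receptor gene P2ry12 at 2.88 (SE 0.85) and Gpr34 at 2.03 (SE 0.59). None of the 15 passed adjusted over all genes. P2ry12, the only 1 of these 4 outside the rule for named genes and chosen after its values were seen, had 488 CPM in shChi3l1 3, 91.4 in shChi3l1 2 and 20.2 in shChi3l1 1, against 21.1 to 41.0 CPM in the shSC libraries. The list score was 2.21 in shChi3l1 3, 0.734 in shChi3l1 2 and -0.742 in shChi3l1 1, and it ranged from -0.869 to -0.252 in shSC libraries (exact two-sided permutation p = 0.229). Without shChi3l1 3 the mean log2 difference dropped from 1.28 to 0.557 (camera adjusted p = 0.000314), and without shChi3l1 1 it was 1.98 (3.47e-16). ShChi3l1 3 was also the highest in B-cell, endothelial and fibroblast and pericyte markers, with scores of 2.62, 1.97 and 1.90.

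**Figure D2:**
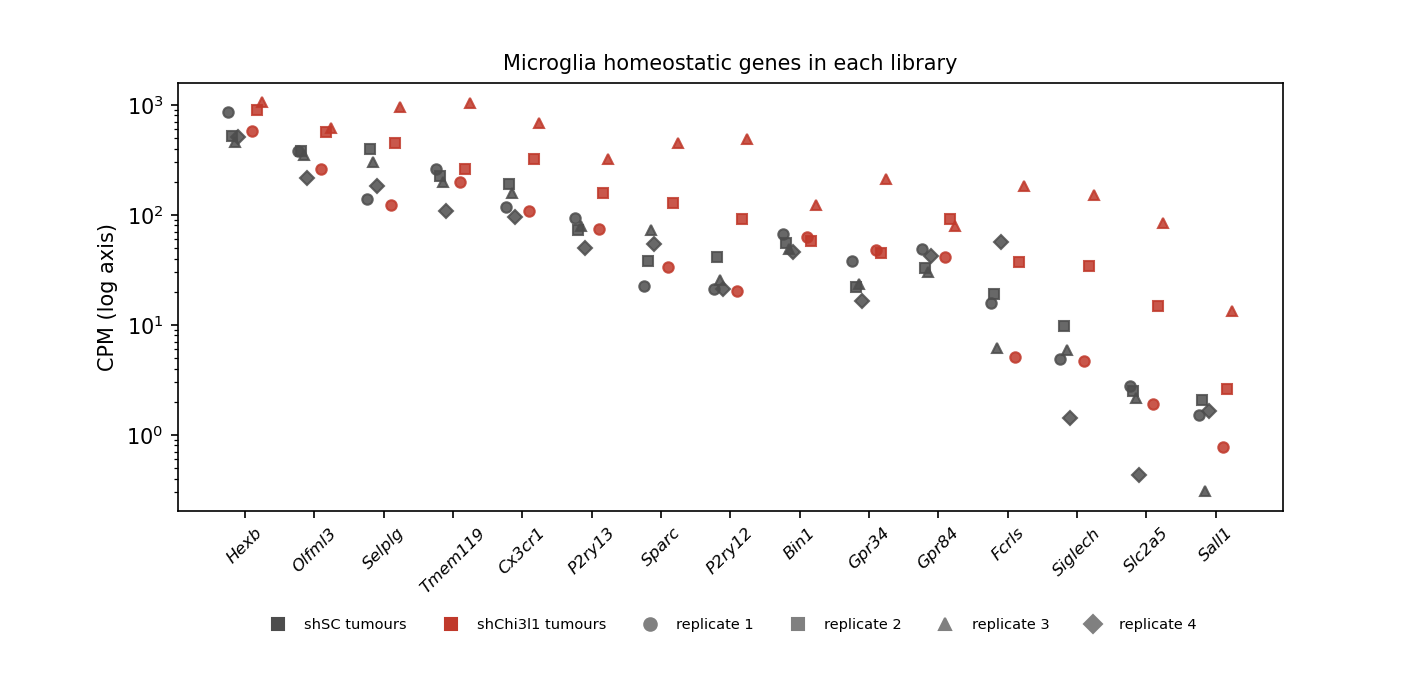
CPM (log axis) of the 15 microglia homeostatic genes, ordered by mean level. Each point is 1 library, coloured by group and shaped by replicate number. Siglech stands at 152 CPM in shChi3l1 3 and between 1.42 and 34.1 CPM in the other libraries.

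Immediate-early and heat-shock genes, which respond quickly to stimulation and to cell stress, rose as a group. Of 25 members 22 were higher, with a median log2 fold change of 0.55 and an adjusted p of 4.78e-08. Its adjusted p with an estimated correlation was 0.288. The transcription factor genes Jund and Egr3 were at 1.21 (SE 0.41) and 1.43 (SE 0.55), and Dnajb1, an Hsp40 co-chaperone gene, was at 1.33 (SE 0.50). Another gene overlaps 52.6% of the exon bases of Jund, and the counts could not separate their reads. No member passed adjusted over the list alone. The list score was 0.320 ± 0.468 (SD, n = 3) in shChi3l1 and -0.240 ± 0.068 (SD, n = 4) in shSC libraries, with an exact two-sided permutation p of 0.0571. The score of 0.842 in shChi3l1 3 was the highest, and without that library the list score differed by 0.299 (SE 0.127) with a camera adjusted p of 0.0107. Without it the 5 heat-shock members had a mean log2 fold change of -0.146 (SE 0.255 over members) in place of 1.127. The 20 immediate-early members had one of 0.367 (SE 0.115 over members) in place of 0.515.

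M1-like and pro-inflammatory macrophage genes rose as a group with all 21 members higher, at a median log2 fold change of 0.35 and an adjusted p of 1.56e-03. With an estimated correlation the adjusted p was 0.42. Cxcl11, a chemokine locus annotated as a polymorphic pseudogene and with 41.7% of its exon bases overlapped by another gene, was at 1.17 (SE 0.53). Ccl5, a T-cell attracting chemokine gene, was at 1.02 (SE 0.52), and the co-stimulatory gene Cd80 at 0.55 (SE 0.38). The call rested on shChi3l1 2, without which the adjusted p was 0.515 and the mean log2 difference 0.097, against 0.378 with all libraries and 0.59 without shChi3l1 3. With the replicate number as a block, which leaves out shSC 4, the mean was 0.552 (adjusted p = 7.86e-07, and an adjusted p of 0.736 with an estimated correlation), and the score was higher in shChi3l1 in all 3 same-numbered pairs. Without the members that other lists share, the mean was 0.328 and the adjusted p 0.0769.

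Interferon-stimulated genes rose with 21 of 25 members higher, at a median log2 fold change of 0.33 and an adjusted p of 8.25e-03. An estimated correlation gave an adjusted p of 0.733. Ddx58, which encodes the RNA sensor RIG-I, was at 1.05 (SE 0.68), Oas3 at 0.92 (SE 0.68) and Ifit2 at 0.66 (SE 0.49). Without shChi3l1 2 camera's direction turned down (adjusted p = 0.858) beside a mean log2 difference of 0.023, against 0.328 with all libraries. Without shSC 4 the mean was 0.152 (adjusted p = 0.486), with the replicate block 0.158 (0.206) and without shSC 2 0.51. MHC class II presentation genes rose with 10 of 12 members higher, at a median of 0.40 and an adjusted p of 2.12e-03. Its adjusted p with an estimated correlation was 0.733. The scores of this list and of B-cell and dendritic-cell markers, whose cells also carry class II, were highest in shChi3l1 3 (0.41, 2.62 and 0.729) and low in shSC 4 (-0.969, -1.75 and -0.906). H2-Oa, a modulator of peptide loading, was at 1.12 (SE 0.55), H2-Ob at 0.73 (SE 0.57) and the protease gene Ctss at 0.53 (SE 0.38). The MHC class II mean of 0.444 became 0.184 without shSC 4 (adjusted p = 0.311), 0.183 with the replicate block (0.179) and 0.103 without shSC 4 and shChi3l1 3 (0.58). The MHC class II score was higher in shChi3l1 in every same-numbered pair (0.125, 0.227 and 0.41 against -0.126, 0.089 and 0.244). With the block fry's unadjusted p was 0.0309 and its adjusted p 0.563.

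Tumour and glial lineage markers, which a pure macrophage sort should lack, fell with 15 of 17 members lower and an adjusted p of 2.33e-03. Their edgeR median was -1.54, and the median on the voom values that camera tests was -0.912. With an estimated correlation its adjusted p was 0.733. Fabp7, a radial-glia fatty-acid binding protein gene, had 141 CPM in shSC 4 and 0.976 to 29.8 CPM in the other libraries. Slc1a3, a glial glutamate transporter gene, went the other way, at 1.00 (SE 0.48). The list score was 2.54 in shSC 4 and -1.87 in shChi3l1 3. The mean of -0.906 became -0.23 without shSC 4 (adjusted p = 0.486), -0.296 without shChi3l1 3 (0.182), -0.031 with the replicate block (0.563) and 0.356 without shSC 4 and shChi3l1 3 (0.108).

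**Figure D3:**
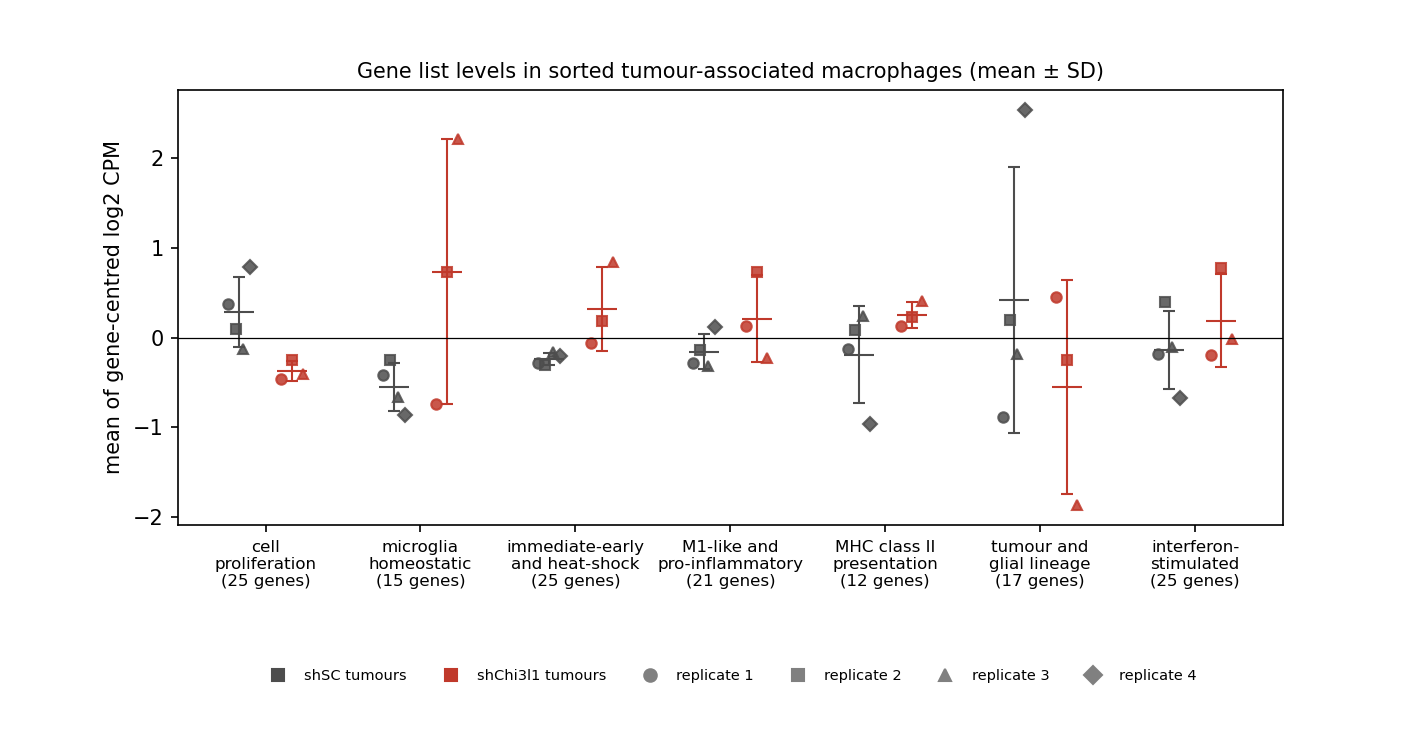
Mean of gene-centred log2 CPM for the 7 lists past an adjusted p of 0.05 under the preset correlation, in order of p. Points are libraries, coloured by group and shaped by replicate number, with a horizontal bar at the group mean and whiskers of 1 SD (n = 3 shChi3l1, n = 4 shSC). The proliferation scores of the 3 shChi3l1 libraries lie between -0.462 and -0.253, below all 4 shSC libraries, and the microglia score reaches 2.21 in shChi3l1 3.

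Macrophage programmes of suppression did not pass the list test, nor did the NF-kB, checkpoint and co-stimulation, and MHC class I lists. M2-like and immunosuppressive genes had 11 of 20 members higher (adjusted p = 0.455). Their members of smallest unadjusted p went both ways: the eotaxin gene Ccl24 was at -5.40 (SE 2.00), Vegfa at 1.25 (SE 0.53) and the scavenger receptor gene Cd163 at 3.06 (SE 1.36). Ccl24 ranged from 1.09 to 1260 CPM within the shSC libraries, and Cd163 stayed at or below 1.99 CPM in every library. Genes linked to C/EBP-beta had 10 of 16 members higher (adjusted p = 0.311), with Cebpa at 1.00 (SE 0.38) and Hp, encoding haptoglobin, at 0.99 (SE 0.61). NF-kB targets had 22 of 25 members higher (adjusted p = 0.0579), with Cd83 at 0.78 (SE 0.38), Tnfaip3 at 0.57 (SE 0.46) and Nfkbiz at 0.43 (SE 0.40). With the replicate block the NF-kB adjusted p was 4.6e-05, and 0.736 with the block and an estimated correlation. Checkpoint and co-stimulation genes had 15 of 20 members higher (adjusted p = 0.297), among them Nectin2 at 0.85 (SE 0.41) and Sirpa, encoding the receptor of CD47, at 0.93 (SE 0.53), while Tnfsf4 was at -1.03 (SE 0.70). MHC class I genes had 15 of 16 members higher (adjusted p = 0.153), with H2-K1 at 0.50 (SE 0.39), H2-D1 at 0.49 (SE 0.40) and Tapbp at 0.53 (SE 0.48). Another gene overlaps 29% of the exon bases of Tapbp, and H2-K1 and H2-D1 are close paralogs between which reads can be misassigned.

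Origin, recruitment and metabolism lists also stayed short of the threshold. Monocyte-derived macrophage genes had 11 of 18 members higher (adjusted p = 0.509), with S100a4 at 1.55 (SE 0.73), Gda at 0.42 (SE 0.34) and Ly6c2 at 0.62 (SE 0.55). Of the exon bases of S100a4, 51.7% are overlapped by another gene. Chemokine and receptor genes had 15 of 26 members higher (adjusted p = 0.367), with the fractalkine receptor gene Cx3cr1 at 1.39 (SE 0.56) and the B-cell attracting Cxcl13 at 1.46 (SE 0.71). Lipid handling and phagocytosis genes had 19 of 25 members higher (adjusted p = 0.0869), with Cd9 at 0.97 (SE 0.40), the lipid-sensing receptor gene Trem2 at 0.74 (SE 0.41) and Cst7 at 0.87 (SE 0.50). The replicate block moved the lipid list to 0.00906, and its adjusted p was 0.736 with the block and an estimated correlation. Hypoxia and glycolysis genes were 12 higher and 13 lower (adjusted p = 0.733), with a camera direction of down and an edgeR median of -0.01 beside a mean of 0.031, and with Hk2 at 0.59 (SE 0.40) and Slc2a1 at 0.46 (SE 0.33). Nuclear-encoded oxidative phosphorylation genes had a mean of -0.125 and an edgeR median of 0.07, and camera's direction was down (adjusted p = 0.124). With the replicate block that list reached 0.00647, and 0.808 with the block and an estimated correlation. Ndufa4 was at -0.68 (SE 0.68), Sdhc at -0.40 (SE 0.41) and Uqcrh at 0.52 (SE 0.66). PI3K-AKT-mTORC1 and FOXO genes had an adjusted p of 0.365, with a camera direction of down beside an edgeR median of 0.04. Its lowest p belonged to Asns, to Trib3, a pseudokinase gene of the amino-acid stress response, at -0.94 (SE 0.40), and to the serine synthesis gene Psat1 at -1.09 (SE 0.56). Matrix and protease genes were split 11 to 11 (adjusted p = 0.153), camera's direction was down with a mean of -0.35, and the edgeR median was just above 0, with Timp2 higher and the collagenase genes Mmp8 at -1.48 (SE 0.57) and Mmp13 at -1.14 (SE 0.47).

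Markers of other cells that the gate could have admitted varied more between libraries than between groups. B-cell markers had 11 of 11 members higher (adjusted p = 0.0755), but Igkc, the kappa constant gene, was at 6921 CPM in shChi3l1 3, 1388 CPM in shSC 3 and at most 658 CPM elsewhere. Ighm was at 1.63 (SE 0.93). T-cell and NK-cell markers had 16 of 22 members lower (adjusted p = 0.453), with the granzyme gene Gzma at -0.07 (SE 0.98) and the perforin gene Prf1 at -0.96 (SE 0.69). With the replicate block the T-cell and NK-cell adjusted p was 2.92e-07 with a mean log2 difference of -0.671 on voom values, and 0.808 with the block and an estimated correlation. Endothelial markers had 10 of 12 members higher (adjusted p = 0.372), with Ly6c1 at 0.78 (SE 0.81) and Slco1a4 at 2.41 (SE 1.11), and the block moved the list to 0.0332, or to an adjusted p of 0.808 with the block and an estimated correlation. Neuron markers had 4 of 6 members higher (adjusted p = 0.421), with Tubb3 at 0.11 (SE 0.91) and Stmn2 at 1.07 (SE 1.07). Oligodendrocyte markers had 8 of 10 members higher (adjusted p = 0.258), with Cnp at 0.00 (SE 0.39) and Aspa at -2.18 (SE 1.14). Fibroblast and pericyte markers had an adjusted p of 0.297 with a mean of -0.106 and an edgeR median of 0.38. Acta2 was at 0.30 (SE 0.93), and the pericyte potassium channel gene Kcnj8, at -1.79 (SE 0.51), was the only other gene that passed when adjusted over its list alone (adjusted p = 0.0376). Neutrophil markers had 5 of 7 members lower (adjusted p = 0.311), with Mmp8 lower as above and Csf3r at 0.98 (SE 0.71). Dendritic-cell markers had 11 of 16 members higher (adjusted p = 0.297), with Siglech higher as above and Ccr7 at -0.14 (SE 0.68). Erythroid genes had 5 of 6 members lower (adjusted p = 0.18), with Hbb-bs at -0.85 (SE 1.08) and Hba-a2 at -1.38 (SE 1.28). The haemoglobin copies are near-identical, so their single-gene counts are uncertain.

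Library measures did not separate the groups. Protein-coding genes with at least 1 read numbered 14200 ± 543 (SD, n = 3) in shChi3l1 and 14650 ± 892 (SD, n = 4) in shSC libraries. Mitochondrially encoded genes took 0.945% ± 0.473 (SD, n = 3) and 1.32% ± 0.547 (SD, n = 4) of reads. The smallest exact two-sided permutation p among 12 library measures was 0.171, for the share taken by the 50 most abundant genes, and its Benjamini-Hochberg adjusted value was 0.823. The design allows no p below 0.0571 for a single measure.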

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

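The tests of single libraries, brain tissue, tumour cells, lymphocytes and dissociation stress were chosen after the list scores had been seen, as were the standard errors between libraries set beside the single-library and length tests, while the other splits and the length bound on p were set before their results.

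Chance cannot be excluded as the source of the list calls. The hairpin split gave 7 lists past the threshold, and 25 of the 35 splits of the 7 libraries gave as many, with 15 in the highest of the others. Among the 8 splits that part all 3 pairs, 6 gave as many, with 10 in the highest other. For genes, the hairpin split gave 0, which all 35 splits reach by definition, so that count says nothing about chance. One other split, shChi3l1 1, shSC 1 and shSC 3 against the rest, called 1481 genes, which points to a structure of the samples unrelated to the hairpin. Its fold changes correlated at -0.579 (Spearman, across 8786 genes, which are not independent) with transcript length. The 547 genes higher in those 3 libraries had a median transcript length of 1464 bases and the 934 lower ones 4853 bases. With offsets for each library's length trend that split called 0 genes.

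Microglia homeostatic genes rose in shChi3l1 under the preset correlation, and 2 of the 35 splits, the real one included, gave an adjusted p as small for this list, chosen out of 29 after its result was seen, as did 2 of the 8 that part every pair. Without shChi3l1 3 camera kept the call (adjusted p = 0.000314), but the list score then differed by 0.547 with a standard error of 0.75 between libraries, so it stays open whether 1 library alone carries the difference. Brain tissue carried into that sort also stays open, with values on both sides. Neuron and oligodendrocyte markers were 0.545 (SE 0.685 over 16 markers) above the shSC mean on the log2 scale. That range includes 1.381, which is 50% of the microglia excess. Endothelial and fibroblast and pericyte scores were highest in shChi3l1 3, at 1.974 and 1.896. Its neuron score of -0.078 lay above shSC 1 (-2.621) but below shSC 2, 3 and 4 (0.132, 0.584 and 0.943). Its oligodendrocyte score of 0.613 lay below shSC 3 (1.243) and above the other shSC libraries (-1.979 to 0.103). Its tumour and glial score of -1.869 was the lowest of all libraries. The length trend is argued against as the whole cause, since it accounted for 0.008 (SE 0.059) of the score difference of 1.285. After its removal camera's adjusted p was 1.91e-11 under the preset correlation, but 0.701 under an estimated one. The hairpin itself remains an untested biological explanation, and shChi3l1 1, with a score of -0.742, lay within the shSC range.

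Proliferation genes fell in shChi3l1 under the preset correlation, but camera's adjusted p was 0.288 under an estimated one. At the preset correlation 2 of the 35 splits, the real one included, gave an adjusted p as small. Of the 8 that part every pair only the real one did (next 2.71e-08), too few splits for a share under 0.05. The score was lower in all 3 pairs. Tumour cells in the shSC 4 sort are argued against as the whole cause, since without shSC 4 the list stayed lower (adjusted p = 7.83e-10) with a score difference of -0.491 (SE 0.159). Length bias is argued against too, since the trend's part was 0.015 (SE 0.028), of the other sign to the score difference of -0.657. After the trend was removed camera's adjusted p was 4e-17 under the preset correlation, but 0.48 under an estimated one. A smaller share of dividing lymphocytes stays open. In edgeR's fit T-cell and NK-cell markers had a mean of -0.21 (SE 0.082 over 22 markers) against the proliferation median of -0.721. With the replicate block their edgeR mean was -0.593 (SE 0.111) against -0.611. B-cell markers had means of 0.879 (SE 0.206 over 11 markers) and, with the block, 0.394 (SE 0.135). These errors leave out the spread between libraries, which was wide. The B-cell score was 0.481 ± 1.96 (SD, n = 3) in shChi3l1 and -0.361 ± 1.868 (SD, n = 4) in shSC libraries. The T-cell and NK-cell score was 0.021 ± 1.151 (SD, n = 3) and -0.016 ± 1.468 (SD, n = 4). It was lower in shChi3l1 in pairs 2 and 3 (-1.308 against 1.052, and 0.676 against 1.377). In pair 1 it was higher (0.696 against -0.819), although proliferation was lower there (-0.462 against 0.376). The 2 libraries highest in proliferation, shSC 4 and shSC 1, had low T-cell and NK-cell scores (-1.672 and -0.819) and low B-cell scores (-1.752 and -2.133). The hairpin itself remains an untested biological explanation.

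Immediate-early and heat-shock genes rose in shChi3l1 under the preset correlation, but camera's adjusted p was 0.288 under an estimated one. At the preset correlation only the real one of the 35 splits gave an adjusted p as small, for a list picked out of 29. The same held among the 8 that part every pair (next 6.66e-05), too few for a share under 0.05. The length trend is argued against as the whole cause, since it accounted for 0.002 (SE 0.071) of the score difference of 0.56. After its removal camera's adjusted p was 1.49e-08 under the preset correlation, but 0.48 under an estimated one. Without shChi3l1 3 the list kept its call at the preset correlation (camera adjusted p = 0.0107, score difference 0.299, SE 0.127 over libraries). The immediate-early members alone differed by 0.38 (SE 0.133) and the heat-shock members by -0.024 (SE 0.447). With 2 shChi3l1 libraries left, the spread is too poorly known to exclude shChi3l1 3 as the only source. For both kinds of member it stays open. A stress of digestion and sorting may have contributed and stays open too. The 5 heat-shock members had a mean log2 fold change of 1.127 (SE 0.371 over members) with all libraries. Without shChi3l1 3 it was -0.146 (SE 0.255 over members). Over libraries, the heat-shock score difference was 0.78 with a standard error of 0.903. The hairpin itself remains an untested biological explanation.

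Among 131 values examined within the 4 shSC libraries, 7 had 1 library far from the other 3, where chance gives 6.6. In shSC 1, Hpgd was highest at 6.241 CPM (others 2.881 to 3.246), Cd300e was highest at 16.382 CPM (others 7.74 to 8.598), and Vegfa was lowest at 34.855 CPM (others 110.9 to 132.1). In shSC 4, Slc2a5 was lowest at 0.43 CPM (others 2.149 to 2.766), Cnp was lowest at 73.1 CPM (others 143.7 to 156.7), and haemoglobin genes took the highest share of reads, 0.00939% (others 0.000518% to 0.0017%). In shSC 3, immunoglobulin genes took 0.3296% of reads (others 0.0253% to 0.0756%).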

How the results depend on the processing

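Removing both doubted libraries, removing overlapped members, the length offsets and both covariates were chosen after the data had been seen. The gene count of 0 held under 19 of 20 alternatives, with 137 to 927 genes at an unadjusted p under 0.05, and DESeq2's Wald test gave 1. The list count of 7 was 15 (9 higher, 6 lower) without shChi3l1 3 and shSC 4, 11 (7 higher, 4 lower) with sample quality weights and 0 with an estimated correlation, and it ranged from 6 without shSC 4 to 14 without shChi3l1 3 or without shSC 3 when 1 library was left out. With an estimated correlation the adjusted p was 0.288 for proliferation and stress, 0.42 for microglia and M1-like genes and 0.733 for MHC class II, interferon-stimulated and tumour genes. With the replicate block the count of genes was 0 and of lists 9; interferon-stimulated (0.206), MHC class II (0.179) and tumour (0.563) lists lost their calls, and NF-kB, lipid, oxidative phosphorylation, endothelial and T-cell lists gained one; it changed no other call. With the block and length offsets, interferon-stimulated genes were at 0.135 and tumour genes at 0.472, while MHC class II genes regained their call (0.0109). Without shChi3l1 3 and shSC 4, MHC class II was at 0.58, and tumour (0.108, now up), endothelial (0.0122, now down) and B-cell lists (0.000834, now down) changed direction. M1-like genes without shared members were at 0.0769, with a mean of 0.328 against 0.378.

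Leaving out 1 library at a time, adjusted p ranged from 2.44e-06 (without shChi3l1 3) to 0.515 (without shChi3l1 2) for M1-like genes, from 0.000151 (without shSC 2) to 0.858 with the direction turned down (without shChi3l1 2) for interferon-stimulated genes, from 5.71e-05 (without shSC 3) to 0.311 (without shSC 4) for MHC class II genes, and from 0.000228 (without shSC 1) to 0.486 (without shSC 4) for tumour markers. Proliferation, microglia and stress genes stayed past the threshold without each library. These leave-out values are all at camera's preset correlation, and with all libraries none of the lists passed under an estimated one. The list T-cell and NK-cell markers was up without shChi3l1 2 (0.00668), shSC 3 (0.0449) and shSC 2 (0.389), and down without shSC 4 (1.02e-05). The list endothelial markers was down without shChi3l1 3 (0.024) and shSC 1 (0.954). Lists short of the threshold gained a call in 63 of 458 values, and 5 reversed past it. The cause was not tested for these changes, beyond the libraries left out. Of 1701 values for named genes, 1604 moved by at most 1 standard error, 97 by more, and 68 had the other sign; none passed the threshold. At the observed dispersion, simulated 2-fold changes were called in 4% of genes, which limits what single genes can show here. That rate is only a guide, since the simulated genes varied independently and without a length trend.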

Other observations

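The observations here were all chosen after the data had been seen, and none has a test that was fixed in advance.

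With each shChi3l1 library set against its same-numbered shSC library, edgeR's quasi-likelihood test with the replicate block had 435 genes at an unadjusted p under 0.05, fewer than the 772 that chance gives if genes were independent, and 4 of them are given here only as values picked by hand. Arg1, encoding arginase, was at -1.79 (SE 0.35), Il6 at 1.36 (SE 0.25), Il23a at 1.65 (SE 0.35) and Vegfa at 1.40 (SE 0.22) on the log2 scale. All 4 had an adjusted p of 1. Arg1 was at 401, 17.9 and 18.1 CPM in shChi3l1 replicates 1 to 3 and at 1170, 115 and 39.9 CPM in shSC replicates 1 to 3. The unpaired shSC 4 had 508 CPM of Arg1, 137 CPM of Il6 and 54.6 CPM of Il23a, the last of which exceeds every shChi3l1 library.

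Tumour marker scores and Y-linked transcripts were both highest in shSC 4, which had 9.8 CPM of 4 Y-linked genes where the others had 0 to 3.11, and 7.65 CPM of Olig2 where the others had 0 to 3.06. Over 7 libraries the score and log2 Y-linked CPM correlated at r = 0.916 (exact permutation p = 0.0149, adjusted over 3 relations 0.0224) and rho = 0.679 (p = 0.11). Without shSC 4 and shChi3l1 3, r was 0.569, so the relation rests on those libraries. Xist was at 12.9 to 62.2 CPM in every library.

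B-cell scores and T-cell and NK-cell scores correlated across the 7 libraries, with r = 0.843 (exact permutation p = 0.0325, adjusted 0.0325) and rho = 0.679 (p = 0.11), and r = 0.969 without shChi3l1 3 and shSC 1. The share of reads in genes over 5000 bases and the oxidative phosphorylation score had r = -0.898 (exact permutation p = 0.00893, adjusted 0.0224) and rho = -0.893 (p = 0.0123). Without shChi3l1 1 and shSC 1, r was -0.443, so that relation rests on those libraries. Across 8786 genes, which are not independent, expression relative to the mean of the other libraries correlated with transcript length at -0.497 and -0.531 in those libraries and at -0.216 in shSC 3, and at 0.297 to 0.532 in the remaining 4.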
